A study of Homo sapiens with 18 samples.

How the data were processed

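Whole synovial tissue was sequenced from 18 patients, 9 with rheumatoid arthritis (RA) and 9 with osteoarthritis (OA), 1 library each, and groups were taken from the sample labels. Sample titles number separate patients, so replicates are separate patients; the replicate numbers used here only name libraries and pair nothing. Per the labels' protocols, libraries were made from polyA RNA of homogenised tissue with a NEBNext Ultra kit. Per the submitters' processing notes, the tools named are bcl2fastq, TopHat2 and HTSeq with genome build hg19, without their order or settings. The annotation release, the strand setting of the counting and any read filters are not given in the sources used here, so antisense, overlapping and near-identical genes are uncertain.

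The authors deposited whole-number counts per Ensembl gene for 57232 genes, with gene coordinates and a gene length in bases per the file headers. The authors also deposited FPKM values per gene. In 100% of nonzero values FPKM equalled the count divided by gene length and by the library's total count, within a relative tolerance of 1e-06, so both tables hold the same measurement on 2 scales. No per-sample column was left unmapped, and no row lacked a gene identifier. Gene symbols came from an Ensembl identifier table for 51058 identifiers, which held 97.9% of counts, and coordinates are those of the deposited tables. Before any table or test, 508 genes (XIST, TSIX and Y-linked genes) were left out, which left 56724. Identical libraries were looked for within groups: the lowest chi-square per degree of freedom between 2 libraries of a group was 16.4, over genes with at least 20 counts in both libraries summed. None was within sampling noise.

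Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, robust dispersion and the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over the 14583 genes kept. Adjusted p-values of single genes are from this test, at a threshold of 0.05, and fold changes are log2 of RA over OA with their standard errors. The common biological coefficient of variation was 0.363 and the median standard error of a log2 fold change 0.2. The fit was tested on simulated counts for the same genes and libraries, with 50 genes changed at each size. It called 37 at a log2 fold of 1, 43 at 1.5, 49 at 2 and 48 at 3, and 6 of its 183 calls were false. Changed genes were drawn only from those above a minimum mean count, and genes were simulated independently. These recoveries therefore do not cover genes with low counts. CPM values carry the TMM scaling, and log2 CPM used a prior count of 2. Total counts per library ran from 2288478 to 8100850. Intervals and tests cover the spread between these patients, except Fisher's exact tests of gene families, which compare genes. Counts without molecular identifiers are not independent molecules.

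Before the data were examined, 42 gene lists were fixed for cell types that synovium or a biopsy can hold and for responses and pathways. The 37 lists with at least 5 measured members were tested with camera in limma 3.58.1, at a preset correlation of 0.01 and with an estimated one. A list score, the mean log2 CPM of the members, was compared by a two-sided exact permutation test over all 48620 splits of 9 against 9, adjusted over the lists. The same kind of test compared mean absolute deviations from the group median. Within each disease 8 pairs of list scores were correlated, a family of 16, with two-sided permutation p-values. Correlations with the haemoglobin score within RA also had 95% percentile intervals from 10000 bootstrap resamples of the 9 libraries. These and the wider 95% Fisher intervals were added after seeing the data. The plan was to draw resamples; with 9 libraries all 362880 orderings were enumerated, which makes these p-values exact. MRC1, PECAM1, SCX, CCL3, CCL4 and MMP12 were list members not analysed here because their symbols had no match.

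Genes named in the text were fixed by rule: the 10 higher and 10 lower genes with the smallest p among those with an adjusted p under 0.05, an absolute log2 fold of at least 1 and at least 5 mean CPM in the higher group, and up to 4 members of each list with the smallest p. Immunoglobulin and T cell receptor segments and HLA genes are given only as counts and sums. Some genes that the rule takes are not reported here. Other list members named as examples, and members of the gene families in the closing part, were chosen after their values were seen. Alternatives fixed beforehand were RLE and upper-quartile factors, no filter and a stricter filter, DESeq2 1.42.0, limma voom, log2 FPKM with 2 pseudocounts, the letter of the library code (P or S, of unstated meaning) as covariate and each letter alone, immunoglobulin or mitochondrial genes left out, other thresholds, fry, median scores and each library left out in turn. Leaving out RA replicates 1 and 8 together, and thinning every library to 2288478 counts, were added after seeing the data. Permutations, correlations and plots used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.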

Results

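Synovium is the tissue that lines joints, and rheumatoid arthritis (RA) is an autoimmune inflammation of it. Whole synovial tissue from 18 patients was profiled by polyA RNA sequencing, with 9 libraries from RA and 9 from osteoarthritis (OA), a degenerative joint disease. The RA tissue came from ultrasound-guided biopsies of the wrist and the OA tissue from material discarded at joint replacement, so disease, joint and way of collection changed together. The labels name no OA joint and give 1 batch for every library. Library totals were lower in RA, with a mean of 3926400 counts (range 2288478 to 5431898) against 5524400 in OA (range 3384215 to 8100850, n = 9 and 9, two-sided exact permutation p = 0.0172). The mitochondrially encoded share of counts was 5.84% ± 1.83 (SD, n = 9) in RA and 4.27% ± 0.877 (SD, n = 9) in OA (exact permutation p = 0.0326).

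The comparison asked which genes differed between RA synovium and the OA comparison tissue. Immediate early transcription factors, which stimuli switch on within minutes, were lower in RA. In that list p was smallest for FOSB, EGR1, JUN and the phosphatase gene DUSP1. Higher in RA were 7 of 9 cytotoxic lymphocyte genes, 8 of 13 infiltrating myeloid genes, 11 of 13 interferon gamma and 12 of 18 type I interferon genes. Of 12 plasma cell genes 4 were higher, 2 without RA replicate 3 or 5 and 7 without RA replicate 6 or OA replicate 3. With an estimated correlation the camera test called none of these lists. Position genes of the HOXC cluster were lower and HOXD10 and HOXD11 higher. Of 14583 genes tested with edgeR, 1655 were called at an adjusted p under 0.05, 923 higher and 732 lower in RA, and 4038 had an unadjusted p under 0.05. In 111 of the called genes all RA libraries lay on one side of all OA libraries, which chance gives a single gene with an exact probability of 4.11e-05. The count was 1957 without RA replicates 1 and 8, a choice made after seeing the data, and 2306 without RA replicate 6. Among the 10 libraries with code letter P alone 59 genes were called, and among the 8 with letter S alone 1136. With limma on log2(FPKM + 1) values 63.6% of calls were higher in RA, against 55.8% in the count test.

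**Figure D1:**
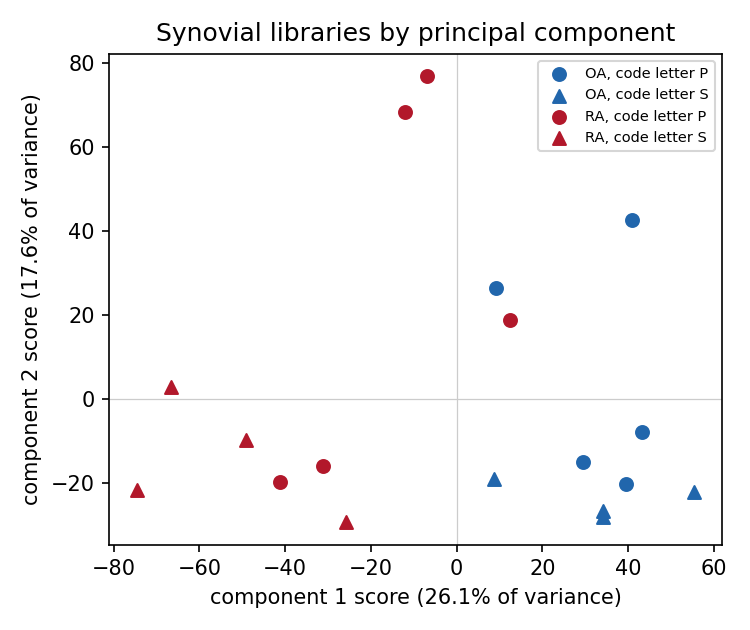
Scores of the 18 libraries on principal components 1 and 2 of log2 CPM, with colour for disease and marker shape for the letter of the library code. Component 1 scores averaged -32.8 ± 28.3 (SD) in RA and 32.8 ± 15.3 in OA, and 2 RA libraries lay at 76.8 and 68.3 on component 2.

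Among the 10 genes with the smallest p that were higher in RA, S100A9 (chromosome 1, 153330330 to 153333503, hg19), an alarmin of myeloid cells, was at 233 ± 130 CPM (SD, n = 9) against 33.4 ± 14.1 in OA. Its log2 fold change was 2.80 ± 0.37 (SE), with an adjusted p of 0.00015. CSF2RB (chromosome 22, 37309670 to 37336491), the common beta chain of the GM-CSF, IL-3 and IL-5 receptors, rose by 1.49 ± 0.19 (adjusted p = 0.000129). GIMAP6 (chromosome 7, 150322463 to 150329473), a GTPase gene of lymphocytes, rose by 1.35 ± 0.17 (adjusted p = 0.000115). C16orf54 (log2 fold change 2.38 ± 0.24), ARHGAP26 (1.08 ± 0.13), NRGN (1.69 ± 0.23), HOXD11 and HOXD10 were also in this set. HCP5 (1.68 ± 0.22) and TBX5-AS1 (2.56 ± 0.34) overlap other genes, and their values are uncertain because the counting is not stated to use strand. Among the 10 that were lower, FOXP2 (chromosome 7, 113726382 to 114333827), a transcription factor gene, fell by 3.26 ± 0.32 on the log2 scale (adjusted p = 6.39e-06). TPD52L1 fell by 2.42 ± 0.24 and the small GTPase gene RHOB by 2.24 ± 0.23. POU3F3 had 7 counts over the 9 RA libraries and 495 over the 9 OA libraries. MT1JP, a metallothionein pseudogene with close copies, had 9 and 966 counts and is uncertain. HOXC10, DUSP1, EGR1, FOSB and JUN completed the set.

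Of 19 immediate early genes, 16 fell in RA and 3 were not called, and the same numbers held adjusted over the list alone. FOSB (chromosome 19, 45971253 to 45978437) was at 14.5 ± 7.15 CPM (SD, n = 9) in RA and 1940 ± 1980 in OA, a log2 fold change of -7.06 ± 0.67 (SE) with an adjusted p of 5.75e-06. EGR1 (chromosome 5, 137801179 to 137805004) fell by 4.43 ± 0.41, JUN (chromosome 1, 59246465 to 59249785) by 3.17 ± 0.32 on the log2 scale. DUSP1 (chromosome 5, 172195093 to 172198198) had a log2 fold change of -3.25 ± 0.25. FOS was at 144 ± 152 CPM in RA and 3530 ± 1600 in OA. The list score, the mean log2 CPM of the members, differed by -2.43 (exact permutation adjusted p = 0.000761, from an unadjusted p of 4.11e-05, the smallest these splits can give), and 9 of 9 RA libraries lay below the OA median. The difference was -2.44 among libraries with code letter P and -2.43 among those with letter S. The camera call had an adjusted p of 7.28e-20, and adjusted p = 0.118 with an estimated correlation.

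Of 12 glucocorticoid response genes, 9 fell in RA, and 10 did so adjusted over the list alone. TSC22D3, a glucocorticoid-induced leucine zipper gene, fell by 1.42 ± 0.20 on the log2 scale, PER1 by 2.12 ± 0.42 and KLF9 by 1.84 ± 0.37. DUSP1 is also a member of the immediate early list. The score difference was -1.54 (exact permutation adjusted p = 0.000761), below the OA median in 9 of 9 RA libraries, and the camera test gave adjusted p = 0.0589 with an estimated correlation. Of 14 genes of TNF, IL-1 and IL-6 signalling, 7 fell and 1 rose, and adjusted over the list alone 8 fell and 2 rose. SOCS3, a feedback inhibitor of cytokine signalling, fell by 3.52 ± 0.45, PTGS2 by 2.5 ± 0.47 and the cytokine gene IL6 by 3.53 ± 0.84 on the log2 scale, while ICAM1, an adhesion molecule gene, rose by 0.75 ± 0.18. The camera call for this list had an adjusted p of 0.0247, and adjusted p = 0.519 with an estimated correlation. Its score difference of -0.83 did not pass the exact permutation test (adjusted p = 0.111). The camera call was lost without RA replicates 1, 6 or 7 or OA replicate 8.

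Position genes, transcription factor genes whose expression records where along a limb a cell arose, moved in both directions. All 3 measured hindlimb genes fell: HOXC10 (chromosome 12, 54378849 to 54384063) from 30.8 ± 7.64 CPM (SD, n = 9) in OA to 1.55 ± 1.2 in RA, a log2 fold change of -4.19 ± 0.32 (SE, adjusted p = 3.21e-07), PITX1 by 2.83 ± 0.41 and HOXC9 by 2.10 ± 0.34. Of 5 forelimb genes, 2 fell (HOXC4 and HOXC6), as they did adjusted over the list alone, and TBX5 had a log2 fold change of 0.24 ± 0.23 (adjusted p = 0.531). The forelimb score differed by -0.31 (exact permutation adjusted p = 0.0535). Of 8 genes on the distal limb list, 3 rose (HOXD9, HOXD10 and HOXD11) and 2 fell (MEIS1 and MEIS2), with the same numbers adjusted over the list alone. Only 1 fell without RA replicate 2 or 5 or OA replicate 3 or 4. HOXD10 (chromosome 2, 176973518 to 176984670) was at 11.6 ± 6.80 CPM in RA and 1.05 ± 0.812 in OA (log2 fold change 3.44 ± 0.45). HOXD11 (chromosome 2, 176968944 to 176974722) had 277 counts over the RA libraries and 6 over the OA libraries, 4 of which had none. HOXD10 and HOXD11 overlap each other, and HOXC6 overlaps HOXC9 and HOXC4, so reads shared between them are uncertain. MEIS2 fell by 1.38 ± 0.20. The distal score difference of 0.53 (exact permutation adjusted p = 0.0496) kept its call in 4 of 18 fits that left out 1 library and turned to -0.21 with the median over members, and it was 0.84 with code letter P and 0.14 with letter S. The median fold change of the distal list was -0.13 and its mean 0.87, and the camera test did not call it (adjusted p = 0.827). Its HOXD and MEIS members offset each other in the score, so the score does not measure them as 1 direction. The list fixed no direction for single members, so a fall of MEIS1 and MEIS2 need not oppose the HOXD rise in limb position.

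**Figure D2:**
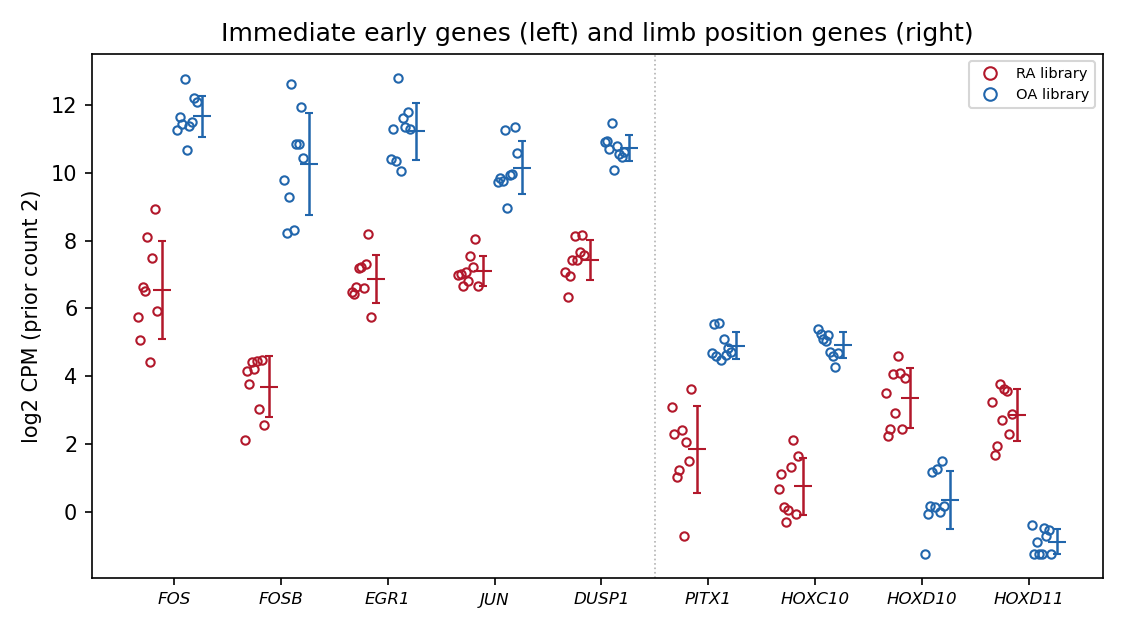
Log2 CPM (prior count 2) of 5 immediate early genes and 4 limb position genes in each RA and OA library, with bars for mean ± SD. For each gene plotted the groups did not overlap, and HOXC10 spanned -0.29 to 2.12 in RA and 4.28 to 5.41 in OA.

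Cytotoxic lymphocyte genes were higher in RA. Of 9 measured members of the NK and cytotoxic list, 7 rose, and 9 did so adjusted over the list alone. GZMB, a granule protease gene, rose by 3.20 ± 0.52 (SE) on the log2 scale to 10.5 ± 6.30 CPM (SD, n = 9), PRF1 by 1.88 ± 0.41 and CD8A by 2.03 ± 0.50. The score difference was 1.94 (exact permutation adjusted p = 0.00355), with 9 of 9 RA libraries above the OA median, and the camera test gave adjusted p = 0.244 with an estimated correlation. Of 12 plasma cell genes, 4 rose, and 10 did so adjusted over the list alone. The count of 4 fell in 12 of 18 fits that left out 1 library, to 2 without RA replicate 3 or 5, and was 7 without RA replicate 6 or OA replicate 3. SLAMF7 rose by 3.49 ± 0.70 and CD38 by 1.68 ± 0.41. The plasma cell score differed by 2.07 (exact permutation adjusted p = 0.00639), above the OA median in 9 of 9 libraries, with a camera adjusted p = 0.292 with an estimated correlation. Immunoglobulin segments summed to a median of 9690 CPM in RA and 160 in OA (exact permutation p = 0.00119), and 14 of 41 tested rose. Of 11 T cell genes 2 rose, and 4 did so adjusted over the list alone. With 1 library left out, 1 rose in 12 of 18 fits, as without RA replicate 2, and 6 without OA replicate 8. CD27 rose by 1.56 ± 0.36, and CD2, at 1.56 ± 0.49, kept its call in 6 of 18 fits that left out 1 library. The T cell score difference of 1.22 (exact permutation adjusted p = 0.0496) kept its call in 5 of those 18 and lost it with the median over members (adjusted p = 0.0848), and the camera adjusted p was 0.455 with an estimated correlation. No B cell gene of 5 was called (1 without OA replicate 3 or 8), and the B cell score differed by 0.50 (exact permutation adjusted p = 0.374) while the median fold change was -0.23. None of 8 lymphoid aggregate genes was called over all genes (1 to 3 in 5 of 18 fits that left out 1 library, 3 without OA replicate 8) and 2 were adjusted over the list alone. That list had a score difference of 0.91 (exact permutation adjusted p = 0.0793) and a camera call with adjusted p = 0.497 with an estimated correlation.

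Genes of infiltrating myeloid cells rose in RA for 8 of 13 members. Adjusted over the list alone 11 rose and 1 fell. FCN1, a monocyte lectin gene, rose by 2.23 ± 0.47, CCR2, a chemokine receptor gene of monocytes, by 2.40 ± 0.54 and S100A8 by 1.75 ± 0.44 on the log2 scale. The score difference was 1.44 (exact permutation adjusted p = 0.0066, and 0.0837 with the median over members), with 7 of 9 RA libraries above the OA median, and the camera adjusted p was 0.244 with an estimated correlation. Tissue-resident macrophage genes did not pass the test in any of 14 members. MERTK, a receptor of these cells, was at 37.7 ± 12.4 CPM (SD, n = 9) in RA and 61.4 ± 23.5 in OA (adjusted p = 0.0812), and the score difference was 0.05 (exact permutation adjusted p = 0.923). The camera direction of this list was down while its mean fold change was 0.09. Of 15 general macrophage genes 3 rose (CD14, FCGR2A and FCER1G), and 4 did so adjusted over the list alone. When 1 library was left out fewer than 3 rose in 12 of 18 fits, and 0 did without RA replicate 2 or OA replicate 4 or 9. The macrophage score differed by 0.61 (exact permutation adjusted p = 0.165), and the camera adjusted p was 0.519 with an estimated correlation. Of 6 dendritic cell genes 1 rose, IL3RA, by 1.38 ± 0.20, and 4 did so adjusted over the list alone. More rose in 8 of the 18 fits, 4 without RA replicate 6. The dendritic score differed by 0.79 (exact permutation adjusted p = 0.00978, and 0.129 with the median over members), with a camera adjusted p = 0.244 with an estimated correlation. Blood markers moved with these groups. HBB, a haemoglobin gene, was at 4420 ± 5670 CPM in RA and 42.6 ± 27.8 in OA (log2 fold change 6.70 ± 0.95), and HBA1 and HBA2, near-identical copies, rose too. All 4 measured neutrophil genes rose, with FCGR3B at 3.32 ± 0.54 and CXCR2 at 3.70 ± 0.65, and FCGR3B shares reads with its close copy FCGR3A. CSF3R, which is also on the infiltrating myeloid list, kept its call in 9 of 18 fits that left out 1 library.

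Interferon genes rose. Of 13 interferon gamma response genes 11 rose, as they did adjusted over the list alone, among them CXCL9, a T cell chemokine gene, by 4.15 ± 0.78 and GBP1 by 2.58 ± 0.38 on the log2 scale. The score difference was 1.59 (exact permutation adjusted p = 0.00639), with 9 of 9 RA libraries above the OA median. The camera adjusted p was 0.244 with an estimated correlation. Of 18 type I interferon genes 12 rose, and 15 did so adjusted over the list alone. IFI27 rose by 1.87 ± 0.36, MX2 by 1.46 ± 0.27 and IFIT3 by 1.18 ± 0.24. Their score differed by 0.90 (exact permutation adjusted p = 0.0186), with camera adjusted p = 0.455 with an estimated correlation. Among libraries with code letter P the differences were 0.92 for interferon gamma (exact permutation p = 0.0714) and 0.51 for type I (p = 0.167), and with letter S they were 2.43 and 1.39 (both p = 0.0286, the smallest that design can give). Of 11 genes of HLA class II presentation 6 rose, and 11 did so adjusted over the list alone, CIITA, the class II transactivator gene, by 1.34 ± 0.30. The count of 6 was 3 in 10 of 18 fits that left out 1 library, as without RA replicate 2, and 10 without RA replicate 6 or OA replicate 2. The score differed by 1.01 (exact permutation adjusted p = 0.0496), a call kept in 3 of those fits and lost with the median over members (adjusted p = 0.0891), with camera adjusted p = 0.455 with an estimated correlation. The 24 HLA genes summed to 15300 ± 6600 CPM (SD, n = 9) in RA and 6390 ± 2030 in OA (exact permutation p = 0.00115).

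**Figure D3:**
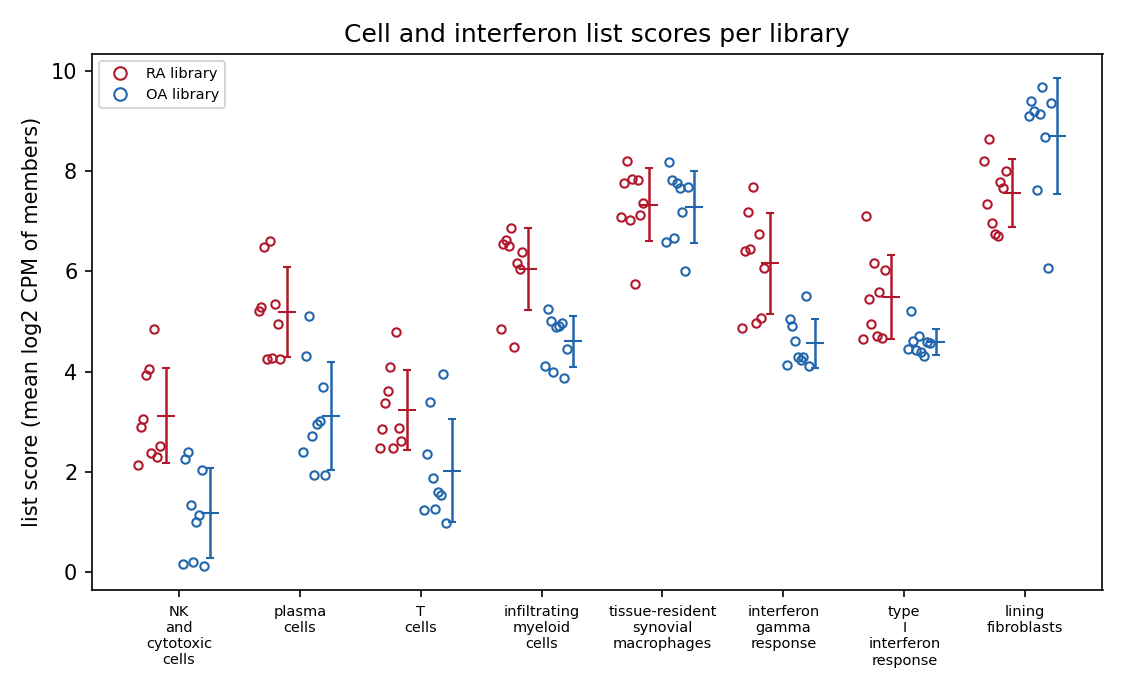
List scores (mean log2 CPM of the measured members) of 8 gene lists in each RA and OA library, with bars for mean ± SD. Cytotoxic scores averaged 3.13 in RA and 1.19 in OA, and tissue-resident macrophage scores 7.33 and 7.28.

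Genes of the fibroblasts that line the joint space were lower in RA for 6 of 12 members, and for 8 adjusted over the list alone. HBEGF, a growth factor gene, fell by 2.02 ± 0.43 and HTRA1, a secreted protease gene, by 1.66 ± 0.45 on the log2 scale. PRG4, which encodes the joint lubricant lubricin, was at 5680 ± 3470 CPM (SD, n = 9) in RA and 19600 ± 12200 in OA (adjusted p = 0.0411), a call kept in 5 of 18 fits that left out 1 library. The count of 6 fell in 17 of 18 fits that left out 1 library, to 2 without OA replicate 6. The score difference of -1.13 did not pass the exact permutation test (adjusted p = 0.0628), and the camera adjusted p was 0.483 with an estimated correlation. Of 16 sublining fibroblast genes 2 fell, as adjusted over the list alone, PDGFRA, a growth factor receptor gene, by 1.21 ± 0.18 and SFRP1, a Wnt inhibitor gene, by 1.72 ± 0.43. That list's score difference was -0.35 (exact permutation adjusted p = 0.228), with camera adjusted p = 0.514 with an estimated correlation. Of 14 complement genes 3 fell, and adjusted over the list alone 4 fell and 1 rose. CFI, a complement inhibitor gene, fell by 1.44 ± 0.27, and the near-identical C4A and C4B are uncertain. The complement score differed by -0.63 (exact permutation adjusted p = 0.0259; 0.0514 without OA replicate 4 and 0.315 with the median over members), with camera adjusted p = 0.455 with an estimated correlation. None of 9 mast cell genes was called, though HPGDS was in 4 of 18 fits that left out 1 library. The mast cell score differed by -0.70 (exact permutation adjusted p = 0.165). The camera call of that list had adjusted p = 0.514 with an estimated correlation. Of 17 Wnt and TGF-beta genes 3 fell, and adjusted over the list alone 3 fell and 1 rose. CCN2, a TGF-beta target gene, fell by 1.88 ± 0.29, and the score differed by -0.12 (exact permutation adjusted p = 0.484).

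Markers of other tissues were measured beside these groups. KRT10 and DSP, 2 of 3 measured skin genes, were called higher in RA, but neither was called in 9 of 18 fits that left out 1 library, and without RA replicate 1 their adjusted p was 0.697 and 0.589. Of 5 peripheral nerve genes 3 rose, including MBP by 0.69 ± 0.16, and only 1 did in 9 of the 18 fits, as without RA replicate 6. The nerve score differed by 0.88 (exact permutation adjusted p = 0.15), by 1.75 among libraries with code letter P (exact permutation p = 0.0159) and by -0.22 among those with letter S (p = 0.571). Of 6 tendon genes 1 rose, TNMD, lost in 6 of the 18 fits with an adjusted p of 0.12 without RA replicate 6, and the score differed by 0.06 (exact permutation adjusted p = 0.923). Of 7 cartilage genes 1 fell, SOX9, by 1.65 ± 0.39, with a score difference of -0.13 (exact permutation adjusted p = 0.865). Of 12 endothelial genes 1 was called, but 0 in 12 of 18 fits that left out 1 library, as without RA replicate 1, and 2 without OA replicate 8, and the score differed by 0.42 (exact permutation adjusted p = 0.282). No member was called among 11 mural, 14 adipocyte, 8 bone and osteoclast or 3 skeletal muscle genes, and the 3 of these lists with a score differed by 0.33, -0.61 and 0.01 (exact permutation adjusted p = 0.535, 0.535 and 0.951). The adipocyte score went opposite ways by code letter, by 0.72 with letter P (exact permutation p = 0.556) and by -2.28 with letter S (p = 0.0286, the smallest that design can give). Of 13 mitochondrially encoded genes 1 was called, MT-CO1 (0.56 ± 0.18), and 4 were adjusted over the list alone. MT-CO1 kept its call in 4 of 18 fits that left out 1 library, and the count was 0 in 13, as without RA replicate 1, and 5 without RA replicate 2. That score differed by 0.36 (exact permutation adjusted p = 0.154), by 0.54 with letter P (exact permutation p = 0.0159) and 0.12 with letter S (p = 0.686), with camera adjusted p = 0.519 with an estimated correlation.

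Of 14 hypoxia response genes 2 rose, EGLN3 by 2.13 ± 0.40 and PDK1 by 1.06 ± 0.29, both of which encode enzymes, and 1 fell, but 0 did in 11 of 18 fits that left out 1 library, as without RA replicate 1. The hypoxia score differed by 0.18 (exact permutation adjusted p = 0.142). Of 11 heat shock genes 1 rose (0 in 8 of the 18 fits, as without RA replicate 2) and 1 fell (0 in 7, as without RA replicate 3, and 3 without RA replicate 1), with a score difference of 0.01 (exact permutation adjusted p = 0.923). No member was called among 13 matrix metalloproteinase and aggrecanase genes (score difference -0.41, exact permutation adjusted p = 0.348), 10 proliferation genes (0.38, adjusted p = 0.484; -0.08 with code letter P and 0.95 with letter S) or 16 ribosomal protein genes (0.03, adjusted p = 0.923). Of 14 targets of drugs used in RA 1 rose, the receptor gene IL6R, by 0.73 ± 0.15 (more in 6 of the 18 fits, 4 without RA replicate 6), and IL6 fell, with a score difference of 0.18 (exact permutation adjusted p = 0.484). Of 15 lipid handling genes 2 rose, FABP5, a fatty acid binding protein gene, by 1.37 ± 0.27, though only 1 did in 10 of the 18 fits, as without RA replicate 3, and the score differed by -0.16 (exact permutation adjusted p = 0.484).

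**Figure D4:**
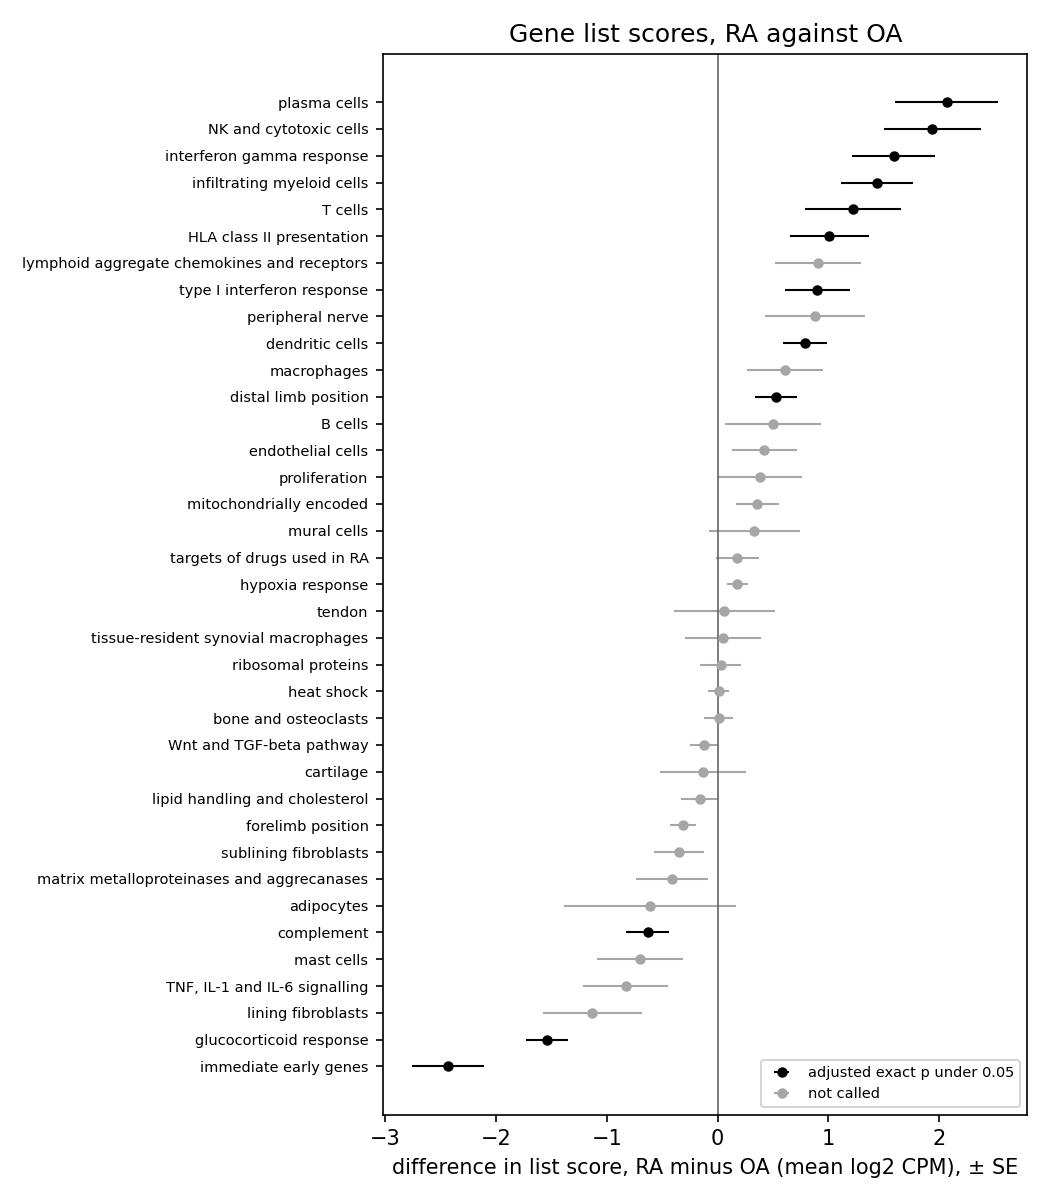
Difference in list score (mean log2 CPM, RA minus OA) for the 37 lists with at least 5 measured members, with bars for ± SE and black points for the 12 lists called by the exact permutation test. Differences ran from -2.43 for immediate early genes to 2.07 for plasma cells.

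Over the 37 lists tested, camera with a preset correlation of 0.01 called 18, and with an estimated correlation it called 0, the lowest adjusted p being 0.0589 for the glucocorticoid list. The preset call for sublining fibroblasts was lost without RA replicate 5, 6 or 7 or OA replicate 1, 4, 7 or 8, that for mast cells without OA replicate 8, that for complement without RA replicate 6, and that for mitochondrially encoded genes without RA replicates 1 and 8 together. The 12 lists called by score kept their direction within each code letter, with an exact permutation p under 0.05 for 5 of 12 among letter P and 9 of 12 among letter S. The spread of list scores within RA and within OA was compared to ask whether patients of one disease varied more. No list passed (0 of 37 by the exact permutation test at an adjusted p under 0.05), and 4 had an unadjusted exact permutation p under 0.05, including the type I interferon list, at p = 0.00765. Leaving out 1 library gave 1 list without RA replicate 1 or 3 and 2 lists without RA replicate 7. Among 16 correlations between list scores within a disease, 6 had an adjusted permutation p under 0.05. In OA, T cell and B cell scores followed each other (Pearson r = 0.97, permutation adjusted p = 0.00018, Spearman rho = 0.97, permutation adjusted p = 0.0026, n = 9), and r was 0.96 without the 2 libraries farthest from the median. In RA the same pair had r = 0.69 (permutation adjusted p = 0.077; rho = 0.70, permutation adjusted p = 0.099) and r = 0.45 without 2 libraries. Tissue-resident and infiltrating myeloid scores followed each other in OA (r = 0.89, permutation adjusted p = 0.011; rho = 0.83, adjusted p = 0.033; 0.79 without 2 libraries). In RA that pair had r = 0.80 (permutation adjusted p = 0.021; rho = 0.75, adjusted p = 0.082; 0.52 without 2 libraries). Macrophage and lining fibroblast scores had r = 0.80 in OA (permutation adjusted p = 0.011; rho = 0.87, adjusted p = 0.024) and 0.35 in RA (permutation adjusted p = 0.42), and the difference between the diseases was not tested. T cell and plasma cell scores had r = 0.80 in OA (permutation adjusted p = 0.03; rho = 0.87), and endothelial and mural scores r = 0.89 in RA (permutation adjusted p = 0.011; rho = 0.72, adjusted p = 0.098).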

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

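The libraries named here stood apart by a test of the gap between the highest or lowest library and its nearest neighbour, fixed before the data were examined, and no test in this part was chosen after the results were seen. Of 430 groups of 9 libraries tested, 31 had such a library, and chance alone gives about 1 in 20. No explanation was tested for these values.

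Skin and proliferation genes stood apart in RA. KRT10 reached 11.3 log2 CPM in 1 RA library against 5.64 in the next, DSP 8.53 against 4.36 and PERP 8.61 against 5.46. The proliferation score reached 5.11 in 1 RA library against 3.15, with CDK1 at 4.54 against 2.51 and TPX2 at 5.12 against 3.26. The tissue-resident macrophage score was lowest in 1 RA library at 5.75 against 7.02, and C1QC was lowest in RA at 6.72 against 8.51. CD74 was lowest in RA at 10.25 against 11.74, C3AR1 at 4.87 against 6.57, BANK1 at 1.28 against 3.28 and NRGN at 3.12 against 4.15. TNFRSF11B was lowest in RA at 0.24 against 3.08, TIMP2 at 9.07 against 10.14 and HOXC9 at -1.23 against 0.44. The value of -1.23 is what the prior count gives a library without counts, so it is not a measured level. MX2 was highest in RA at 7.12 against 5.90.

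In OA, the adipocyte score was lowest in 1 library at 2.08 against 4.62. The type I interferon score was highest at 5.21 against 4.71, with IFIT2 at 5.49 against 4.48. ITGB8 was lowest in OA at 2.77 against 6.05, PDGFRA at 8.19 against 8.83, EMCN at 4.65 against 5.35 and HPGDS at 2.94 against 4.10. CSF3R was lowest in OA at 2.80 against 4.15 and ARHGAP26 at 4.22 against 4.53. BATF3 was highest in OA at 3.48 against 2.53, HSPA8 at 9.55 against 9.17 and FABP5 at 5.93 against 5.09. Immunoglobulin segments took 4.14% of counts in 1 RA library, and 1.19% in 1 OA library against 0.52%. The 10 most abundant genes took 16.0% of counts in 1 RA library against 11.4% in the next.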

How the results depend on the processing

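Leaving out RA replicates 1 and 8 together and thinning every library were chosen after seeing the data; all other alternatives were fixed beforehand. The 1655 calls (923 higher, 732 lower) became 2594 with DESeq2 (1400 and 1194), 894 with unfiltered log2(FPKM + 1) (503 and 391), 59 with code letter P alone (17 and 42), 583 at an adjusted p under 0.01 (292 and 291) and 688 at 2-fold or more (334 and 354). Without a filter on low counts 581 were higher. Under every other alternative run the count stayed within 1.5 times, 1226 to 2306 when 1 library was left out, 1957 without the 2 RA libraries and 1345 after thinning. A stricter threshold lowers the 0.01 and 2-fold counts by construction; for the others, the P count included, the cause was not tested. Camera calls went from 18 to 0 with an estimated correlation, and list score calls from 12 to 6 with the median over members, which ended those of T cells, infiltrating myeloid cells, dendritic cells, HLA class II, complement and distal limb genes. List spread calls were 0, and 0 to 2 when 1 library was left out (RA replicates 1, 3 and 7 gave calls). The distal limb score turned to -0.21 with the median over members. KRT10 turned to -0.14 with DESeq2 and -0.13 without the 2 RA libraries or without RA replicate 1 alone (up to 3.3 without another library). With code letter S alone DSP turned to -0.22. RA replicate 1 has letter P, so the fit with letter S and the fit without the 2 RA libraries both lacked it. Neither KRT10 nor DSP was called without that library. The cause of the DESeq2 value was not tested. Of the named genes' values with 1 library left out, 2849 stayed on their side of the threshold, 183 lost and 81 gained a call, and 1 turned; under the other alternatives the numbers were 2575, 230, 82 and 3. At the smallest simulated change, a log2 fold of 1, 37 of 50 changed genes were called. Smaller changes, and changes in genes with low counts, were not simulated.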

Other observations

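The 17 gene families in the next paragraph, the thinning tests, both tests of position genes, the intervals of the hypoxia and heat shock scores and of the haemoglobin correlations, which decide the blood tests, and the 4-gene neutrophil correlation were chosen after results were seen; the other tests were written down before the result each measures. Every pattern below was noticed in the same libraries it was tested on.

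Gene families were compared with all tested genes by Fisher's exact test, with a set of clock genes picked by function counted among them. There were 34 tests over 17 families, with 5 families called for higher and 6 for lower members. The test counts family members as independent, though they can move together across the same patients. Its p-values therefore do not measure the spread between patients. All 7 GIMAP genes, GTPases of lymphocytes, rose in RA (adjusted Fisher's exact p = 1.35e-07), with GIMAP4 at a log2 fold change of 1.17 ± 0.19 (SE). Of 40 proteasome subunit genes 12 rose (adjusted p = 4.67e-05), PSMB8, an immunoproteasome gene, by 1.00 ± 0.19. Of 9 LILR receptor genes of myeloid cells 5 rose (adjusted p = 0.000695), LILRB2 by 1.80 ± 0.34, and of 9 S100A genes 3 rose (adjusted p = 0.0492). Of 9 metallothionein genes, whose proteins bind metals, 6 fell (adjusted Fisher's exact p = 1.95e-05), the pseudogene MT1JP among them. MT1E was at 55.5 ± 28 CPM (SD, n = 9) in RA and 339 ± 229 in OA, though close copies make single members uncertain. All 4 tested HOXC genes fell (adjusted Fisher's exact p = 5.32e-05) and 3 of 5 HOXD genes rose (adjusted Fisher's exact p = 0.0111), while none of 5 HOXB genes was called. Because HOXC6 overlaps HOXC9 and HOXC4, and HOXD10 overlaps HOXD11, these members may share reads.

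Of 14 KLF transcription factor genes 5 fell (adjusted Fisher's exact p = 0.00242), KLF4 by 2.48 ± 0.34 on the log2 scale, and of 15 ADAMTS protease genes 4 fell (adjusted p = 0.0233), ADAMTS1 by 2.36 ± 0.48. Of 34 genes with KCN symbols, which are not all channel genes, 6 fell and 3 rose (adjusted Fisher's exact p for lower members 0.0237). Of 17 clock genes, a set picked by function rather than 1 family, 4 fell (adjusted Fisher's exact p = 0.03), namely PER1, PER3, BHLHE40 and NR1D2. That call depends on the choice of members. BMAL1, which runs in the opposite phase, had a log2 fold change of 0.90 ± 0.31 (edgeR adjusted p = 0.0628). No hour of collection was used here. Of 31 collagen genes 2 fell (adjusted p = 1), and the HOXA, DUSP, SLC2A and SIGLEC families were not called in either direction.

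The 1655 genes called between RA and OA were set against other splits of the 18 libraries into 9 and 9. Of 100 splits drawn, the real one included, 1 gave as many calls, the real one, and the highest of the others called 1 gene. Chance is therefore an unlikely source of the count, but 100 splits cannot show a share below 1 in 100.

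Immediate early genes were lower in RA. The lowest OA score lay 0.58 above the highest RA score, which argues against a few OA libraries as the source, and after thinning all libraries to the smallest total 100% of the 16 calls were kept, which argues against smaller RA libraries. Lack of oxygen in the OA tissue and a general stress response stay open: the hypoxia score differed by 0.18 (exact permutation p = 0.065, 95% interval -0.01 to 0.38) and the heat shock score by 0.01 (exact permutation p = 0.885, interval -0.18 to 0.21). Neither was lower in RA, but both intervals reach below 0, and a p that misses the threshold was a poor bound to have set against either. Disease, joint and the way tissue was taken also remain untested, since the design ties them together.

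Called higher in RA were 7 of 9 cytotoxic, 8 of 13 infiltrating myeloid and 4 of 4 neutrophil genes. So were 4 of 12 plasma cell genes (2 without RA replicate 3 or 5, 7 without RA replicate 6 or OA replicate 3) and the T cell score. CSF3R counts in both the neutrophil and the infiltrating myeloid list, and kept its call in 9 of 18 fits that left out 1 library. The T cell and infiltrating myeloid scores lost their calls with the median over members, and haemoglobin genes were higher too. Blood as the whole source needs a score that follows the haemoglobin score within the 9 RA libraries, at an r above 0.6 as set beforehand. The values argue against it for plasma cell genes (r = -0.49, permutation p = 0.18, 95% bootstrap interval -0.94 to -0.13). Their rho was -0.52 (permutation p = 0.16, interval up to 0.23), and r was -0.71 without the 2 farthest libraries. They also argue against it for infiltrating myeloid genes (r = -0.60, permutation p = 0.085, interval -0.91 to -0.37). There rho was -0.87 (permutation p = 0.0045, up to -0.46), and r was -0.58 without 2. T cell genes are left undecided (r = -0.15, permutation p = 0.69, interval -0.78 to 0.37). Their rho was -0.38 (permutation p = 0.31, up to 0.43), and r was -0.37 without 2. Fisher intervals of r were wider, -0.87 to 0.25 for plasma cell, -0.74 to 0.57 for T cell and -0.90 to 0.10 for infiltrating myeloid genes. All of these stayed below 0.6, the T cell one by too little to decide with 9 libraries. The rule written beforehand asked T cell and infiltrating myeloid genes for an r below 0 with a permutation p under 0.05, and neither met it. For the 3 neutrophil genes named next the Fisher interval was -0.05 to 0.91. The bounds set beforehand against blood were poor, since a higher plasma cell score is the pattern itself. An r that must differ from 0 also asks more than an r below 0.6. A smaller share from blood is not excluded, and cytotoxic genes were not tested. For the neutrophil genes FCGR3B, CXCR2 and CSF3R r was 0.63 (permutation p = 0.062, interval 0.29 to 0.91; rho = 0.77, permutation p = 0.021; 0.65 without 2) and with MNDA added 0.56 (permutation p = 0.11; rho = 0.55, permutation p = 0.13; 0.62 without 2), so for these blood and tissue cells cannot be told apart with 9 libraries. After thinning, 83.3% of the 6 called T, B and plasma cell genes kept their call, which argues against smaller libraries, and RA itself stays open as an untested explanation.

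Limb position genes differed in both directions. A lower share of fibroblasts in RA would lower these genes together, yet 3 of 16 were called higher while 7 were called lower. The joint sampled is a candidate explanation that stays open: of 6 genes named for it 4 were called in the stated direction, TBX5 was not called and TBX4 was not measured. RA tissue was from the wrist in every case and the labels name no OA joint, so joint and disease cannot be told apart here.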
